A study of Caenorhabditis elegans with 2 samples.

How the data were processed

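The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists from Caenorhabditis elegans whole animals of strain RW12290, in which CRISPR insertion placed a TY1, EGFP and 3xFLAG tag on the endogenous cebp-1 gene on chromosome X. Per the labels, young adults of 62 hours, synchronised by larval starvation after bleaching, were fragmented by sonication to a size range of 200 to 800 bp, and the tagged protein was precipitated with an antibody against GFP. The antibody field of the labels reads cebp-1 and the description names anti-GFP, and the description was followed. There was 1 group of 2 biological replicates, each with its own biosample, and no treated, untagged or input sample was used here.

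The authors called peaks against a control alignment on assembly ce11 and ranked them by irreproducible discovery rate (IDR), per the notes deposited with the files; the peak caller, its version and its settings are not given in the sources used here. IDR compares the order of peaks in a pair of lists and gives each peak the expected rate at which peaks at least as strong fail to repeat. The files held 4 ranked lists and 4 thresholded lists: 1 pair for each replicate alone and 2 pairs for the series, called conservative and optimal here. The deposited score column held whole numbers up to 1000, with 830 as the lowest value in each thresholded list. The second score per peak is the authors' signal value, whose scaling to depth or control is not stated, so it was used only to rank and describe peaks within a list. The deposited −log10 of the global IDR was taken from the ranked list matched to each thresholded list, and no thresholded peak had a global IDR above 0.01. Each series thresholded list was matched to the ranked list that contains its intervals. The ranked list matched to the conservative list also gave the signal values of both lists that IDR compared, and these columns were not assigned to samples. A replicate's signal at a named gene is that of the overlapping peak in its own ranked list. Depth is unknown, because no read counts were in the files used here, and no background from control samples could be given beside the values.

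The coordinates of ce11 were read on the WBcel235 assembly, which is the same build, with chromosomes I to V and X of that reference containing every peak. Genes were taken from the Ensembl annotation of WBcel235, with 19973 protein-coding genes on the nuclear chromosomes. A promoter was 1000 bp upstream to 200 bp downstream of any annotated 5′ end of a protein-coding gene, and a gene was called bound when a summit of the conservative list lay in its promoter. A summit was assigned in the order promoter, exon, intron, non-coding gene and intergenic.

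The share of each replicate's thresholded peaks that overlapped a thresholded peak of the other replicate by at least 1 bp was compared with 1000 random placements on the same chromosomes in a one-sided permutation test. Features were compared with 1000 random placements in a two-sided permutation test. Chromosome counts were tested with a two-sided exact binomial test against chromosome length. Sequence motifs within 100 bp of the summit were compared with a window of equal length centred 500 bp away, on alternating sides, by a two-sided exact McNemar test. There were 23 motifs, including 2 scrambled controls, and every 6-mer was tested in the same way with both strands joined. The 38 gene lists were tested by a two-sided Fisher's exact test against the 10098 protein-coding genes with any ranked peak in the promoter. Strong and weak peaks were the upper and lower 25% by signal value, compared by Fisher's exact test. All families of tests were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Shares carry 95% Wilson intervals, which cover counting error only and treat peaks as independent. P-values over peaks or genes describe these lists and do not measure the spread between animals.

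The comparisons, tests, motifs, gene lists and the rule for named genes were set before the data were examined. The rule took cebp-1, the genes at the 25 strongest conservative peaks, up to 4 strongest bound members of each list mentioned, all bound members of the DLK-1 and p38 lists, the genes at the 5 strongest unshared peaks of each replicate, and the 5 strongest peaks with the consensus outside promoters. The search of 8-mers and the tests of TTGCGAAA were added after the data were seen. To test the leading 8-mer on peaks that had not served to find it, the search was run on chromosomes I, III and V and its leader was tested on II, IV and X.

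Alternatives covered the optimal list, stricter IDR, each replicate's own list, merged peaks, other promoter and window sizes, shuffled and random-promoter controls, other backgrounds and other overlap rules. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The procedures were tested on simulated data. A word planted in 150 of 1500 random genomic windows was measured at an excess of 9.87% of windows, all 3 of its 6-mers were found, and windows with nothing planted gave 0. Those windows lay at random positions, so the simulation does not cover calls that follow from a difference in base composition between summits and flanks. Of 5 planted gene lists among 38, 5 were found, with 1 false call. Of 1000 simulated intervals with 400 planted overlaps, 406 overlapped.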

Results

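CEBP-1 is a bZIP transcription factor of the C/EBP family with known roles in axon regeneration and stress and immune responses. Its binding in young adult C. elegans was mapped by anti-GFP ChIP-seq of an endogenously tagged protein in 2 biological replicates. The series' conservative list, which rests on the comparison of the replicates, held 1546 peaks covering 0.419% of the nuclear genome, with a median width of 304 bp. The optimal list held 1969 peaks, the list of replicate 1 held 1488 and that of replicate 2 held 797. Signal values below are the authors' own scores for each peak. A value of the series list has no error, so the values of both replicates are given for the genes described most closely. Read depth is unknown.

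The first comparison was between the replicates. Of the 797 peaks of replicate 2, 665 overlapped a peak of replicate 1 (83.4%, 95% Wilson interval 80.7 to 85.9%), against a mean of 0.799% for random placements (one-sided permutation p = 0.001, the smallest that 1000 draws can give). Of the 1488 peaks of replicate 1, 668 overlapped a peak of replicate 2 (44.9%, 42.4 to 47.4%; random mean 0.423%, one-sided permutation p = 0.001). The unshared peaks were the weaker ones in each list. In replicate 1 the median signal was 114 for shared and 59.2 for unshared peaks, and in replicate 2 it was 79.6 and 54.01. Most unshared peaks had a counterpart below the threshold. With shared peaks counted as well, 781 of replicate 2's 797 peaks (97.99%) and 1425 of replicate 1's 1488 (95.8%) overlapped some ranked peak of the other. Random placements gave 18.1% and 21.1%. Across the 50793 ranked peaks of the series, which are not independent replicates, the signal values of the compared lists had a Spearman correlation of 0.276. Among the 1546 conservative peaks it was 0.653. IDR selected those peaks on the same pair of lists, so a higher value there follows in part from the selection.

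The peak with the highest signal lay upstream of nipi-3, which encodes a Tribbles-family pseudokinase known as a negative regulator of CEBP-1. It spanned chromosome X 15607479 to 15607978 (ce11), with its summit 262 bp upstream of the annotated 5′ end and a signal of 3014 (1712 in replicate 1 and 1276 in replicate 2). The tagged gene was itself bound. A peak at X 1454326 to 1454757, with its summit 654 bp upstream of cebp-1 and outside any annotated gene, ranked 6 in the conservative and optimal lists and 7 in each replicate's list. Its signal was 1267 in the conservative list, 728.7 in replicate 1 and 522.6 in replicate 2. Among the 5 strongest peaks were those at the promoters of ftt-2, a 14-3-3 protein (signal 1814, with 952.3 and 794.3 in replicates 1 and 2), and xbp-1, the bZIP factor of the endoplasmic reticulum (ER) unfolded protein response (1301, with 772.9 and 516.9). The xbp-1 peak spanned III 4193601 to 4193926, with its summit 36 bp upstream of the 5′ end.

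The other strongest promoter peaks lay at Y37B11A.3, the elongation factor gene eef-1A.2, T28F4.5, frm-10, a pair of neighbouring genes at IV 15646672 to 15647004 (WBGene00194913 is the nearer), and the capping enzyme gene cel-1, which shares its peak with the nucleoporin gene npp-14. Then came icd-1 with vps-32.1, plrg-1, C05G5.2, the kinesin heavy chain gene unc-116, the beta-tubulin gene tbb-2, the exchanger gene nhx-5, npp-6 with the centrosomal spd-5, abhd-5.2, the synaptobrevin gene snb-1 and Y58A7A.3. Their signals ran from 1224 at Y37B11A.3 to 741.2 at Y58A7A.3. The remaining 5 of the 25 strongest peaks had no promoter. The peak at V 14200045 to 14200471, second in the list with a signal of 2133, was intergenic and lay 3887 bp downstream of the nearest 5′ end, that of atfs-1. A pair of peaks on X, at 16930719 to 16931609 inside the non-coding gene C30E1.9 and at 16929445 to 16929855 in intergenic sequence, had C30E1.4 as the nearest gene. The other 2 lay in introns of dhc-4 on III, with col-94 as the nearest 5′ end, and of Y43F8B.2 on V. All 25 peaks were in the thresholded lists of both replicates.

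The sequence under the summits was compared with flanks of the same peaks. The C/EBP and PAR bZIP consensus TTRCGYAA was rare: 30 of 1546 peaks held it (1.94%, 95% Wilson interval 1.36 to 2.76%), against 14 flanks (0.906%, 0.540 to 1.51%), with exact McNemar p = 0.0226 and 0.0434 after adjustment over the motifs. The difference did not pass against shuffled windows, which held the consensus at 1.94% (exact McNemar p = 1), or against random promoter sites at 1.36% (Fisher's exact p = 0.259). With overlapping peaks merged and with a window of 150 bp the exact McNemar p was 0.184 and 0.111. The excess was larger in each replicate's own list, at 2.55% against 0.672% in replicate 1 and 2.01% against 0.376% in replicate 2 (exact McNemar adjusted p = 0.000203 and 0.0127). Within 50 bp of the summit the shares were 1.42% and 0.388% (exact McNemar adjusted p = 0.00855). At a global IDR of at most 0.001 it was 0.0433, and 0.0776 after adjustment over the motifs. A broader C/EBP core with a free centre, TTGCNNAA, was found in 614 peaks (39.7%) and 317 flanks (20.5%; exact McNemar adjusted p = 7.13e-29). This core includes TTGCGAAA, the sequence described below, which was in 442 summit windows and 30 flanks. Of the 23 motifs, 10 were more frequent at summits, and 6 in the peaks with a global IDR of at most 0.001. Among the 10 were the GAGA repeat (6.92% against 1.81%), the GC box (10.03% against 4.08%), the AP-1 site (4.85% against 1.68%) and the CACGTG E-box (8.22% against 4.27%). The C/EBP-ATF composite TTGCATCA and the C/EBP variant TTGCGTAA were also among them (exact McNemar adjusted p = 0.00392 and 0.00786), while TTGCGCAA and TTACGTAA were not. Against shuffled windows TTGCATCA passed (1.81% against 0.647%, exact McNemar adjusted p = 0.0107) and TTGCGTAA did not (exact McNemar adjusted p = 0.554). In the list of replicate 2 alone neither passed (exact McNemar adjusted p = 0.237 and 0.443). The TATA box was less frequent at summits (15.6% against 19.9%; exact McNemar adjusted p = 0.0052), as was the SKN-1 site (7.76% against 10.7%; exact McNemar adjusted p = 0.0115). Against shuffled windows the TATA box was more frequent at summits (15.6% against 11.2%, exact McNemar adjusted p = 0.000738). The SKN-1 site did not pass there (7.76% against 7.44%, exact McNemar adjusted p = 0.817). In the lists of replicates 1 and 2 alone, the SKN-1 site did not pass (exact McNemar adjusted p = 0.929 and 0.194). The TATA box passed in replicate 1 and not in replicate 2 (exact McNemar adjusted p = 0.0329 and 0.194). The scrambled control TTCGRYAA was lower at summits without passing the threshold (3.23% against 4.72%; exact McNemar adjusted p = 0.0682), and the other control was in 0 of 1546 windows of either kind.

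The open search gave a different leading sequence. The 6-mer TGCGAA was in 35.0% of summit windows and 8.54% of flanks, and TCGCAA in 33.4% and 7.18% (exact McNemar adjusted p = 1.31e-69 and 3.33e-69). Of all 6-mers, 512 were more and 395 less frequent at summits. Summit windows had a GC content of 42.4% ± 7.66 (SD over windows) and flanks 36.2% ± 7.47. Extended to 8-mers, the search was led by TTGCGAAA, in 442 of 1546 summit windows (28.6%, 26.4 to 30.9%) and 30 flanks (1.94%, 1.36 to 2.76%; exact McNemar adjusted p = 1.14e-96). It begins with the TTGC of the C/EBP site, and the fixed consensus TTRCGYAA does not include it. The broader core TTGCNNAA does include it, and 442 of that core's 614 peaks and 30 of its 317 flanks held TTGCGAAA. With those windows set aside, the core remained in fewer peaks than flanks by count. That count is over fewer summit windows than flanks, no longer paired, and was not tested. The excess of the core at summits is therefore not shown apart from that of TTGCGAAA. The sequence was picked from these same peaks. The search on chromosomes I, III and V also ranked TTGCGAAA first, and on the 777 peaks of II, IV and X it was in 27.7% of summit windows (24.6 to 30.9%) and 1.80% of flanks (1.08 to 3.00%; exact McNemar p = 3.88e-50). Its centre lay a median of 20.5 bp from the summit. Of the 25 strongest peaks, 23 held it. Near nipi-3 it occurred at X 15607638 to 15607645 and 15607761 to 15607768, at cebp-1 at X 1454520 to 1454527, at ftt-2 at X 11605964 to 11605971 and at xbp-1 at III 4193757 to 4193764. The exceptions were the eef-1A.2 peak, which held TTGCGTAA, and the peak at IV 15646672 to 15647004.

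**Figure D1:**
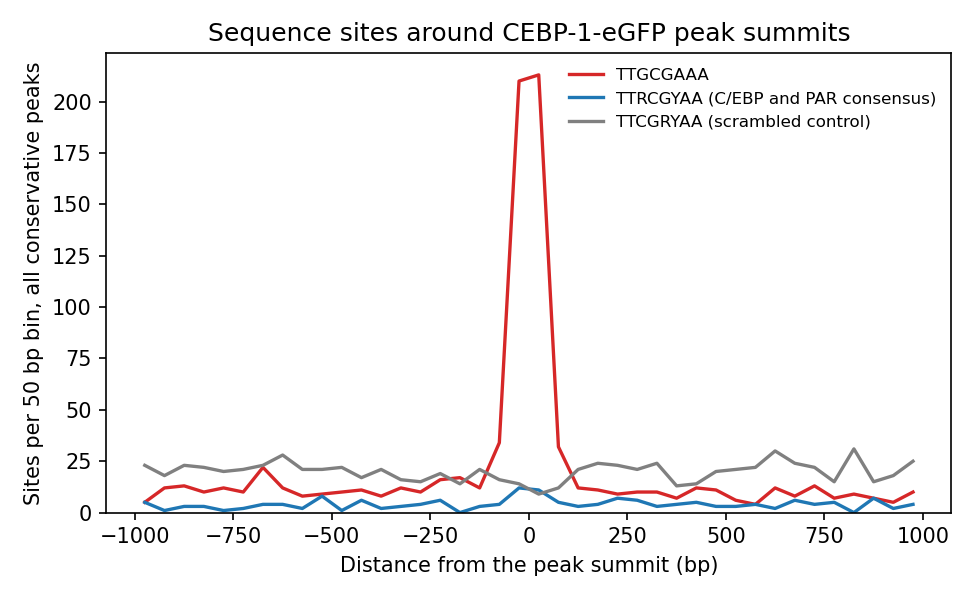
Number of sites per 50 bp bin (vertical axis) against the distance from the summit in bp (horizontal axis) over all 1546 conservative peaks. TTGCGAAA rises to 210 and 213 sites in the bins beside the summit, while the consensus TTRCGYAA and the scrambled control TTCGRYAA stay at or below 12 and 31 sites.

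Binding strength was compared with sequence and position. TTGCGAAA was in 59.8% of the strongest 25% of peaks and 9.85% of the weakest 25%, with 386 peaks in each (Fisher's exact p = 2.54e-51). Peaks with no TTGCGAAA had a median signal of 103 (interquartile range 85.3 to 140.6, n = 1104), peaks with 1 site 182 (118 to 295, n = 406) and peaks with 2 or more 224 (134 to 412, n = 36). The consensus TTRCGYAA was in 15 of the strongest and 6 of the weakest peaks (3.89% against 1.55%), which did not pass (Fisher's exact p = 0.0743). It passed in the list of replicate 2 alone (difference 6.53 percentage points, Fisher's exact p = 0.000199), at a global IDR of at most 0.001 (5.88, Fisher's exact p = 0.00155), in the optimal list (2.44, Fisher's exact p = 0.00702), with merged peaks (3.03, Fisher's exact p = 0.0177) and ranked by IDR (2.59, Fisher's exact p = 0.0388). Between the peaks above and below the median signal the difference was 0.776 (Fisher's exact p = 0.357). Promoter summits made up 65.0% of the strongest peaks (60.1 to 69.6%) and 48.4% of the weakest (43.5 to 53.4%; Fisher's exact p = 4.49e-06).

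**Figure D2:**
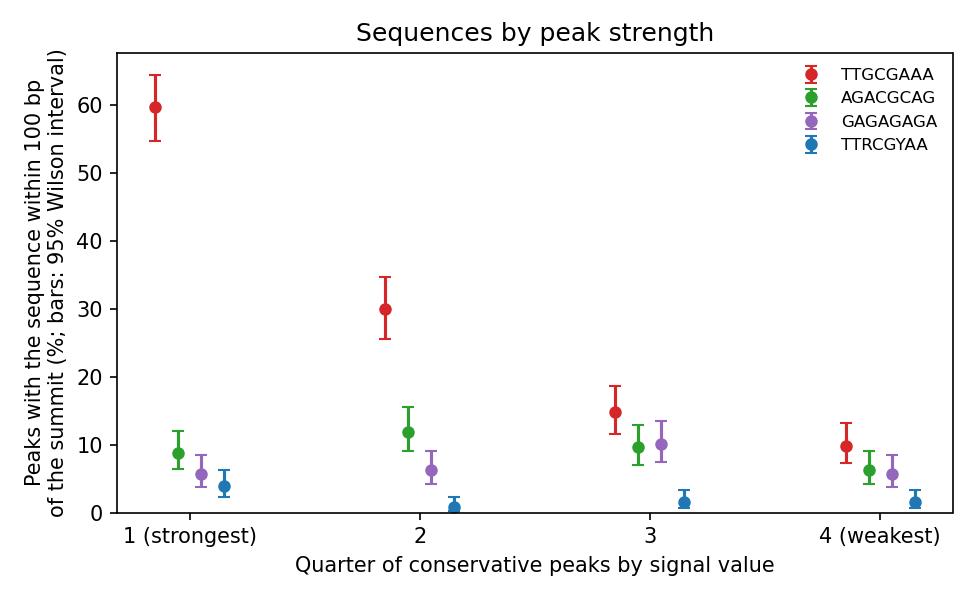
Share of peaks with each sequence within 100 bp of the summit (vertical axis, %, with 95% Wilson intervals as bars) in 4 groups of conservative peaks ordered by signal value (horizontal axis, strongest to weakest). TTGCGAAA falls from 59.7% to 9.85%, while AGACGCAG, GAGAGAGA and TTRCGYAA stay at or below 11.9%.

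Summits lay mainly in promoters. Of the 1546 summits, 879 were in a promoter (56.9%, 54.4 to 59.3%), against a mean of 25.9% for random positions (permutation adjusted p = 0.00333). Exons held 4.08% against 21.7% and introns 14.04% against 27.4% (permutation adjusted p = 0.00333 for both). Intergenic sequence held 21.1% against 21.7% and non-coding genes 3.95% against 3.32%, and neither passed the permutation test (adjusted p = 0.595 and 0.222). Against random ranked peaks outside the list, which were intergenic in 17.01% of cases, the intergenic share was higher (permutation adjusted p = 0.0025). Promoter summits lay a median of 230 bp upstream of the nearest 5′ end. Chromosome X held 329 summits (21.3%, 19.3 to 23.4%, against 17.7% of the genome; exact binomial adjusted p = 0.00153) and chromosome III 261 (16.9%, 15.1 to 18.8%, against 13.8%; exact binomial adjusted p = 0.00153). Chromosomes IV and V held fewer than their length gives, at 14.6% against 17.5% and 17.5% against 20.9% (exact binomial adjusted p = 0.00475 and 0.0018). In the list of replicate 2 alone, the exact binomial adjusted p was 0.0749 for X, 0.0537 for III and 0.0749 for IV, and for X it was 0.0999 at a global IDR of at most 0.001.

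Promoter peaks were assigned to 1010 protein-coding genes, 10% of the 10098 background genes. Of the 38 gene lists, 9 were bound more often than other genes and 2 less often. ER unfolded protein response genes had 9 of 21 members bound (42.9%, odds ratio 6.80; Fisher's exact adjusted p = 0.000507), led by xbp-1 and followed by the disulfide isomerase gene pdi-6 (signal 614.7, with 356.7 and 268.8 in replicates 1 and 2), cdc-48.1 (353.1) and the BiP homologue hsp-3 (206.7). Translation was represented by 13 of 32 translation factors (40.6%, odds ratio 6.22; Fisher's exact adjusted p = 6.66e-05), led by eef-1A.2, pab-2, iff-2 and eef-1A.1, and by 22 of 69 ribosomal protein genes (31.9%, odds ratio 4.28; Fisher's exact adjusted p = 9.05e-06), led by rpl-3 (612.2), rpl-35 (508.4), rpl-15 (489.8) and rpl-20 (327.4). Oxidative phosphorylation genes had 12 of 32 bound (37.5%, odds ratio 5.45; Fisher's exact adjusted p = 0.000302), led by nduf-2.2, cox-5B, ucr-2.1 and cox-5A. These 4 lists passed the threshold under each of the 11 alternatives that changed the peaks, promoters, background or null, with the highest Fisher's exact adjusted p, 0.0486 for translation factors and oxidative phosphorylation, in the list of replicate 2 alone. The alternative null of random ranked peaks favours a pass, since such peaks lay in promoters less often than the listed ones.

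Autophagy and lysosome genes had 12 of 35 bound (34.3%; Fisher's exact adjusted p = 0.000507), led by the receptor gene sqst-1, lgg-1, epg-7 and epg-9. Chromatin and polymerase II regulators had 13 of 39 (33.3%; Fisher's exact adjusted p = 0.00048), led by utx-1, cbp-1, ash-2 and cdk-7. The bZIP transcription factors had 9 of 27 (33.3%; Fisher's exact adjusted p = 0.00407), with xbp-1, cebp-1, zip-2 (591.6, with 305.5 and 276.2 in replicates 1 and 2) and jun-1 (392.5) the strongest. In the list of replicate 2 alone these 3 lists no longer passed, with Fisher's exact adjusted p of 0.0601, 0.0727 and 0.0666. The autophagy list also did not pass at a global IDR of at most 0.001 (Fisher's exact adjusted p = 0.167). Splicing genes had 9 of 36 bound (25%; Fisher's exact adjusted p = 0.032), led by mog-1, mog-4, lsm-7 and prp-19. Heat shock genes had 5 of 15 (33.3%; Fisher's exact adjusted p = 0.0437), the strongest being hsp-1, dnj-13, hsp-110 and hsp-90, and gave a Fisher's exact adjusted p of 0.0511 in the list of replicate 1 alone. When each summit was given only to the gene with the nearest 5′ end, splicing and heat shock genes gave Fisher's exact adjusted p of 0.866 and 0.280. With promoters of 500 bp upstream to 100 bp downstream, splicing genes and bZIP factors gave 0.0992 and 0.0932 (Fisher's exact, adjusted).

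Chemoreceptor genes were bound less often, 7 of 348 (2.01% against 10.3% of other genes; Fisher's exact adjusted p = 1.87e-07), the strongest being sri-5, sre-23, srh-269 and srv-1. Collagen and cuticle genes had 1 of 71 bound, col-185 (1.41% against 10.1%; Fisher's exact adjusted p = 0.0334). In the lists of replicate 1 and replicate 2 alone, at a global IDR of at most 0.001 and with the nearest gene only, the collagen list gave Fisher's exact adjusted p of 0.086, 0.102, 0.0697 and 0.149. With random ranked peaks in place of genes as the null, neither list passed the permutation test (adjusted p = 0.245 and 0.614). Ranked peaks outside the list lay in promoters in a mean of 27.8% of cases, against 56.9% of listed summits. This null therefore expects few bound genes, a mean of 12.7 chemoreceptor and 3.08 collagen genes. A shortage can hardly show against it, so it does not decide the question for either list. Under that null 4 further lists passed: mitochondrial stress response, F-box proteins, nuclear hormone receptors and cytochrome P450s (permutation adjusted p = 0.0076, 0.0076, 0.019 and 0.0351). A pass there can follow from the promoter excess of the listed peaks alone. Nuclear hormone receptors passed with 16 bound against a mean of 7.59 expected, though 9.99% of other genes were bound. Against other genes, F-box proteins had 19 of 127 bound (14.96%; Fisher's exact adjusted p = 0.172), led by fbxc-19, fbxa-108, fbxc-54 and fbxa-37. Nuclear hormone receptors had 16 of 149 (10.7%; Fisher's exact adjusted p = 0.85), led by nhr-56, nhr-3, nhr-154 and nhr-117, and cytochrome P450s 6 of 38 (15.8%; Fisher's exact adjusted p = 0.513), led by cyp-33C6 and cyp-33C7, which share a peak, cyp-33C8 and cyp-25A4. The pathways in which CEBP-1 is best known did not pass as lists. The DLK-1 and KGB-1 axon regeneration list had 4 of 15 members bound (26.7%; Fisher's exact adjusted p = 0.15): nipi-3, cebp-1, the phosphatase gene vhp-1 (160.2, with 80.8 and 74.4 in replicates 1 and 2) and the receptor kinase gene svh-2 (89.8, with 50.1 and 41.7). The p38 immune signalling list had 5 of 17 (29.4%; Fisher's exact adjusted p = 0.0699): nipi-3, zip-2, skn-1 (208.6, with 118.7 and 83.1), vhp-1 and hlh-30 (98.6, with 38.9 and 50.8). In the list of replicate 2 alone and at a global IDR of at most 0.001, svh-2 and hlh-30 had no promoter peak. Against all protein-coding genes as background, which include genes with no ranked peak, both lists passed (Fisher's exact adjusted p = 0.0447 for DLK-1 and 0.0133 for p38). The p38 list also passed with promoters of 2000 bp upstream to 500 bp downstream and with the nearest gene only (Fisher's exact adjusted p = 0.0267 and 0.0407).

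Other lists tied to earlier work on C/EBP factors and stress did not pass either. Immune effectors had 3 of 29 bound (Fisher's exact adjusted p = 1), with irg-2, an infection response gene, at a signal of 685.8, clec-60 at 100.3 and spp-18 between them. Replicate 2 had no ranked peak at spp-18, and the clec-60 peak was in neither replicate's own thresholded list. Lipid metabolism genes had 5 of 40 bound (12.5%; Fisher's exact adjusted p = 0.751), led by dgat-2 (517.4), plin-1 (276.9), lpin-1 (126.7) and pcyt-1 (111.9). Mitochondrial stress response genes had 5 of 18 bound (27.8%; Fisher's exact adjusted p = 0.0821), led by cbp-1, hsp-60, ubl-5 and jmjd-1.2. That list passed in 5 alternatives, among them the list of replicate 1 alone (Fisher's exact adjusted p = 0.0104) and the optimal list (Fisher's exact adjusted p = 0.016), and not in the list of replicate 2 alone (Fisher's exact adjusted p = 0.496). Insulin signalling genes had 5 of 22 bound (22.7%; Fisher's exact adjusted p = 0.157), led by ftt-2, rheb-1, par-5 and akt-2, and passed with promoters of 2000 bp upstream to 500 bp downstream (Fisher's exact adjusted p = 0.0271).

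**Figure D3:**
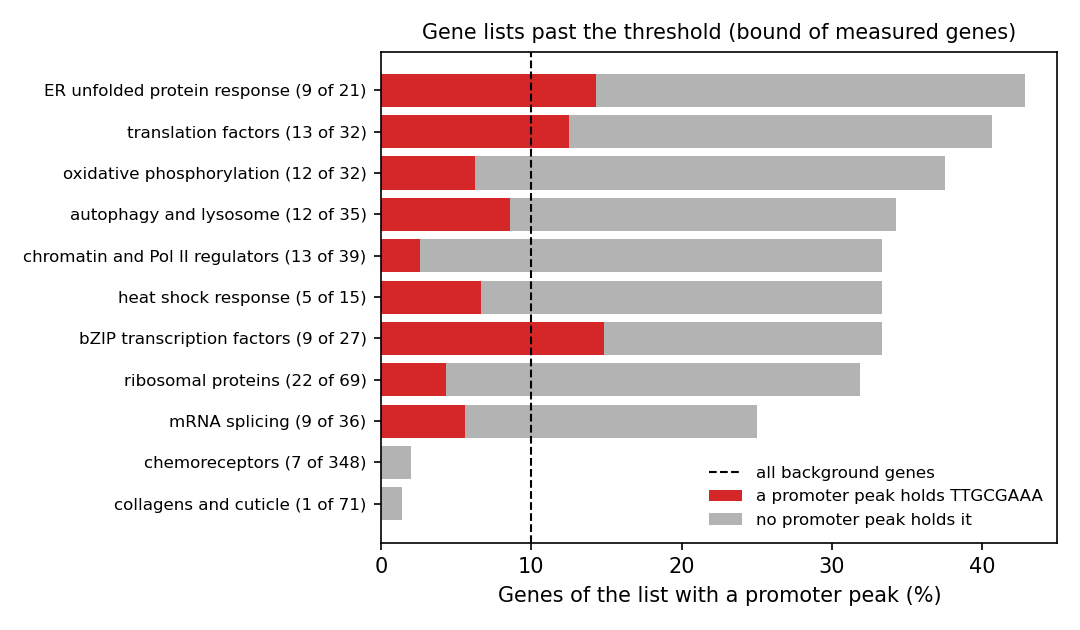
Share of each list's measured genes with a promoter peak (horizontal axis, %) for the 11 lists past the threshold (vertical axis, with bound and measured genes). Red is the part with TTGCGAAA at a promoter peak, grey the part without, and the dashed line the 10% of all background genes. The share runs from 1.41% for collagens to 42.9% for the ER unfolded protein response.

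The strongest peaks thresholded in only 1 replicate were of moderate rank. In replicate 1 they began at rank 161 and lay at pho-9 (177, with 53.65 for the ranked peak of replicate 2), did-2 (172), sek-3 (161), upstream of gldi-3 (156) and near T20G5.12 (144.5). In replicate 2 they began at rank 205 and lay near srg-33, at ubc-3, near srd-43, near cec-4 and inside F22G12.4, with signals from 108.7 down to 80.7. Of these, the peak near cec-4 overlapped no ranked peak of replicate 1. Outside promoters, the strongest peaks with the consensus TTRCGYAA lay upstream of M163.11 (X 14476650 to 14476942, signal 725.9), upstream of K07D4.2 (342.2), in an intron of ppfr-1 (300.5), in the non-coding gene linc-128 (275.8) with cmd-1 as nearest gene, and near C25F9.11 (104.8).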

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

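The ranked lists hold strong peaks that the thresholded lists leave out. In the series list, 41 ranked peaks had a global IDR of at most 0.01 and were absent from the conservative list. The strongest of these, at X 15810941 to 15811160, had a signal of 2148, and 1 ranked peak was stronger. All 41 summits were intergenic. The notes with the deposited files name 1 further input for the thresholded lists that the ranked lists do not have, whose content was not used here. The test of repeated sequence was chosen after the result was seen.

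The values argue against the left-out peaks carrying the sequence of the listed ones: 1 of 41 held TTGCGAAA (2.44%), against 44.8% (95% Wilson interval 41.3 to 48.3%) of listed peaks above the median signal. A fixed set of regions removed from every list may account for the omission, since 0 of the 5800 thresholded peaks of the 4 lists overlapped any of the 64 left-out stretches. Repeated sequence may be what the 41 peaks share: a median of 97.4% of their bases was soft-masked in the reference (95.1 to 98.2% for the peaks left out of the other lists), against a median of 23.4% and an upper quartile of 37.4% for listed peaks. Whether the signal there is binding or an excess of reads in repeats stays open without read coverage or a control sample, and no biological explanation was tested.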

How the results depend on the processing

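The alternatives at a global IDR of 0.001, at a signal of at least 20 and with random ranked peaks as the null for gene lists, and every test of TTGCGAAA, were chosen after the data were seen. The planned limit of 0.01 left out no peak, so it says nothing and is not counted. The replicate overlap, the promoter share, the promoter difference between strong and weak peaks, the number of 6-mers and both TTGCGAAA results kept their direction and side of the threshold under every other alternative run for them, with TTGCGAAA above its control by 24.1 to 39.6 percentage points. The signal correlation moved from 0.276 to 0.653 in the conservative list, 0.299 for non-overlapping peaks and 0.508 as Pearson's r of log2 values. The conservative list was selected by IDR on the same pair of lists. The share on X did not pass without replicate 1 (20.45 to 20.56% over the runs that left out 1 replicate) or at an IDR of 0.001 (20.2%). The excess of TTRCGYAA, 1.03 percentage points, passed with 1 replicate left out (1.63 to 1.88), in the optimal list (1.02), within 50 bp (1.03) and at a signal of at least 20 (1.09). It ended with merged peaks (0.689), a 150 bp window (0.841), random promoter sites (0.582) and shuffled windows (0), and at an IDR of 0.001 it passed before adjustment over the motifs and not after (adjusted exact McNemar p = 0.0776). Its difference between strong and weak peaks, 2.33 percentage points, passed in the optimal list (2.44), with merged peaks (3.03), at an IDR of 0.001 (5.88), ranked by IDR (2.59) and without replicate 1 (2.42 to 6.53 with 1 replicate left out), and was 0.776 between peaks above and below the median signal. At an IDR of 0.001, 6 motifs in place of 10 were more frequent. With 1 replicate left out, 7 to 10 gene lists passed in place of 11. The 10 that passed without replicate 2 include the mitochondrial stress response, which is not among the 11. The shorter lists hold fewer peaks, and neither that nor any other cause of these changes was tested. Over single lists, 390 of the outcomes kept their call, 15 lost it and 13 gained it, 5 for the mitochondrial stress response, 3 for p38 signalling and 1 each for the DLK-1, insulin, F-box, nuclear hormone receptor and cytochrome P450 lists. The gains of the F-box, nuclear hormone receptor and cytochrome P450 lists came only under the null of random ranked peaks, which favours a pass. Unknown depth limits any reading of why replicate 2 has fewer peaks.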

Other observations

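The tests in this part were chosen after TTGCGAAA had been found in the same peaks. The genome holds 7892 copies of TTGCGAAA on the nuclear chromosomes, and 505 lay in a conservative peak (6.40%, 95% Wilson interval 5.88 to 6.96%). Occupied copies were most frequent in promoters (313 of 2396, 13.1%, 11.8 to 14.5%) and least in exons (8 of 920, 0.870%, 0.441 to 1.71%), with introns at 2.65% and intergenic sequence at 6.12%. Summits of all peaks also lay mainly in promoters and seldom in exons (56.9% and 4.08%, against 25.9% and 21.7% of random positions). The order of features therefore does not show by itself that copies in promoters are preferred. Peaks with the sequence were in the list of replicate 1 in 91.6% of cases with 1 copy and 67.8% with none, and in that of replicate 2 in 66.3% and 43.5%. A second sequence, AGACGCAG, was in 141 summit windows and 16 flanks (exact McNemar adjusted p = 1.71e-22). It was found in 6.33% of peaks with TTGCGAAA and 10.2% of the others (odds ratio 0.593, Fisher's exact p = 0.0186). Among the strongest peaks without TTGCGAAA were those at ikke-1, rpl-3 and zip-2, named after their values were seen.

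The tables argue against 3 technical explanations for TTGCGAAA at summits. Base composition would give the sequence in shuffled windows as well, and they held it in 2.78% of cases against 28.6% (26.4 to 30.9%) at summits. Random promoter positions held it in 2.16%, against 31.2% (28.2 to 34.3%) of promoter summits. A repeat family would place it in masked sequence, and 9.73% (7.30 to 12.9%) of the windows with it had it in soft-masked bases alone. A candidate explanation is direct recognition by CEBP-1 or by a partner bZIP protein, but the design has no group for either and no biological explanation was tested.

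The 9 gene lists bound more often than other genes held 103 bound genes, of which 22 (21.4%) had TTGCGAAA at a promoter peak, against 312 of 907 other bound genes (34.4%), and the odds ratio of 0.518 (Fisher's exact p = 0.00779) argues against the sequence as the reason why the 9 lists as a set stand out. By single list the share ran from 7.69% for chromatin and polymerase II regulators to 44.4% for bZIP factors. None of the 9 differed from other bound genes alone (Fisher's exact adjusted p of at least 0.5925). Counted by genes bound with the sequence alone, none of the 9 passed (Fisher's exact adjusted p of at least 0.154). Their odds ratios then ran from 0.769 for chromatin and polymerase II regulators to 5.13 for bZIP factors, so the lists differ in this. With only genes bound without the sequence counted, 7 of the 9 lists still passed, from ribosomal proteins (19 of 69, odds ratio 5.42, Fisher's exact adjusted p = 2.79e-06) to splicing (odds ratio 3.39, Fisher's exact adjusted p = 0.0374). The other 2 did not pass. Heat shock genes had 4 bound in place of 5, with an odds ratio of 5.09 in place of 4.52 (Fisher's exact adjusted p = 0.057). The bZIP genes had 5 bound in place of 9, with 3.18 in place of 4.53 (Fisher's exact adjusted p = 0.108). Fewer genes were counted as bound in the lists and in the background, so these changes do not tell whether the sequence is the cause. By signal, the rule set for weak peaks, a share clearly above or below 50%, gave no decision. A peak above the median signal of promoter peaks was found for 57.3% (47.6 to 66.4%) of the 103 genes, an interval that includes 50%, and for 54.6% of the other bound genes. These shares argue against weak peaks as the whole source for the 103 genes as a set, which would leave few of them with such a peak. At a global IDR of at most 0.001, all 9 lists except autophagy still passed. Their odds ratios ran from 3.36 for chromatin and polymerase II regulators (Fisher's exact adjusted p = 0.0376) to 9.48 for ER unfolded protein response genes (Fisher's exact adjusted p = 0.000187). This argues against less reproducible peaks as the whole source for the lists that passed. Among genes with a peak above that median signal, TTGCGAAA was at 35.6% of 59 listed and 50.9% of 495 other genes (Fisher's exact p = 0.0279). Signal common to open promoters of highly expressed genes, whichever protein is precipitated, may contribute and was not tested, since no untagged or other-factor sample was used here.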
